A study of Mus musculus with 10 samples.

How the data were processed

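Mouse bone marrow cells were sorted into 2 groups of 5 libraries, labelled HSC and LSC. Per the labels' protocols, total RNA was extracted with a miRNeasy kit, mRNA was reverse-transcribed and amplified by the Geo-seq method for small samples, and libraries were built with a TruePrep kit, in which a transposase cuts the cDNA and adds adapters. Amplification of little RNA can widen the spread of low genes. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2, with no role or order given. Strandedness and the annotation release are not given in the sources used here. Reads of near-identical copies, overlapping genes and antisense genes may therefore be shared.

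The authors deposited 1 table of FPKM values, normalized for library size and gene length, for 51456 Ensembl gene IDs and 10 libraries. FPKM values are not counts, so a test on a log scale was used, as fixed before the data were examined. Of the IDs, 51246 matched GENCODE M21 (GRCm38/mm10) and took their symbols and coordinates from it, and 210 did not match. No other column of per-sample values was present, and groups followed the labels.

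Total counts were not analysed here. Low values were checked for steps of whole fragments, after multiplying by gene length. Between 57.5% and 73.2% of low values in a library were whole within 0.05 of a step, which gave an estimated depth of 13280000 to 27680000 fragments in the HSC-labelled and 16750000 to 35240000 in the LSC-labelled libraries, with HSC-labelled replicate 3 the shallowest. The steps did not recover whole reads for nearly all genes, so no count test was run. At such depth a gene below 1 FPKM rests on few fragments, and a fold change on the log2(FPKM + 1) scale understates the change of low genes.

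Genes with at least 1 FPKM in at least 5 libraries were tested (13431) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on group, moderated variance with a mean trend, two-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 fold changes are LSC-labelled minus HSC-labelled. SDs are of FPKM over n = 5 libraries, and SEs of single genes are limma's moderated ones. SEs of list medians are over the list's members on the deposited values, taken as independent, which they are not. Gene annotation and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

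A total of 32 gene lists was fixed before the data were examined: sort markers, haematopoietic stem cell genes, MLL-fusion target genes, granulocyte-monocyte progenitor genes, nucleoporins, nuclear transport receptors and Ran cycle, ferroptosis suppressors, ferroptosis promoters, iron handling genes, cell-cycle genes, cell-cycle inhibitors and quiescence genes, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol and fatty acid synthesis, ATF4 and amino acid response, interferon response, p53 targets, BCL2 family, immediate early and stress genes, MHC class II, markers of erythroid cells, megakaryocytes and platelets, B cells, T and NK cells, neutrophils, monocytes and macrophages, mast cells, basophils and eosinophils, dendritic cells, endothelium and stroma, mitochondrially encoded genes, and sex-linked genes. They were written from general knowledge, not from these samples, and 21 genes stand in at least 2 lists. The 31 lists with at least 5 members tested were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation called 0 of them (smallest adjusted p = 0.151, with 4 lists under 0.05 before adjustment), where the preset one called 15. Fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes, called 26.

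Genes were named by a rule fixed in advance: Nup214; every sort marker; the 5 largest rises and 5 largest falls among called genes with no overlap between groups and a mean of at least 10 FPKM in the higher group, leaving out unnamed gene models; 2 called members of largest change with a mean of at least 1 FPKM in each list on the cells and processes of the study, 1 in each further program, and the most abundant member of each list of other cells; and every sex-linked gene. Further members given as examples were chosen after their values were seen. Some genes that the rule takes are not reported here.

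The fit was tested on simulated data for this comparison, with values drawn from the real means and spreads of the 13431 genes. Of 100 genes changed 2-fold 89% were called and of 100 changed 1.5-fold 56%. The changed genes were picked among those with a mean level, on the log2 scale, above that of 5 FPKM, so these rates do not cover lower genes. Unchanged genes made 7.64% of the calls, and besides the shifted list 0 of 30 lists were called. Only 200 of the 13431 genes were changed, where the real comparison called 5513. The shares recovered and falsely called depend on how many genes change, so they may differ in the real data. Each gene was drawn independently, so members of a simulated list were uncorrelated. The list result therefore does not show how often camera at the preset correlation falsely calls lists of correlated genes. The alternatives were the pseudocounts 0.1 and 0.01, no filter, a mean of at least 5 FPKM, a TPM scale, median-of-ratios scaling, quantile normalization, robust moderation, array weights, removal of GC and length trends (fitted as splines over the 99.9% of genes with both values), a block for the replicate number alone and with that removal, genes on X and Y left out, each library left out in turn, and the other list tests. After the data were seen, the runs without HSC-labelled replicates 1 and 2 (Y-linked genes, other cells) and without replicates 3 and 4 (ribosomal RNA share) were added.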

Results

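The series measured the transcriptomes of mouse bone marrow cells sorted by flow cytometry. One group was labelled haematopoietic stem cells (HSC), lineage-negative cells of wild-type C57BL/6J mice with Sca-1, c-Kit and CD150 and without CD48 on the surface. The other was labelled leukaemia stem cells (LSC), taken from mice with acute myeloid leukaemia driven by the MLL-AF9 fusion gene, and sorted as lineage-negative, Sca-1-negative cells that carry c-Kit, CD34 and the Fc gamma receptors CD16/32. Each group held 5 libraries, and the deposited table gave a value in FPKM, fragments per kilobase of gene scaled to library size, for 51456 genes in each of the 10. The FPKM values of a library summed to between 472651 and 499850, and 12895 to 14172 genes per library reached 1 FPKM. Ribosomal RNA took 5.15% to 9.33% of the FPKM sum in the HSC-labelled libraries and 4.41% to 5.72% in the LSC-labelled ones. The labels number the libraries 1 to 5 in both groups and do not say whether they came from separate mice, so the p-values measure only the spread between these libraries.

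The series title names nucleoporin 214, leukaemia stem cells and ferroptosis, and the comparison asks which genes differ between leukaemic and normal stem cells. By the labels, the groups differ in disease and in sort gate at once, so the effects of disease and gate cannot be told apart. The genes for the sorted surface proteins were read first, as a check on the labels in RNA and not in the surface protein itself. Ly6a, which encodes Sca-1 and defines the HSC gate, stood at 0.920 ± 0.917 FPKM (SD, n = 5) in the HSC-labelled libraries and 74.2 ± 24.8 (n = 5) in the LSC-labelled ones, a log2 fold change of 5.33 (SE 0.297, limma adjusted p = 4.389e-07). Slamf1, which encodes CD150, also ran against the labels, at 0.494 ± 0.270 and 2.85 ± 0.319 FPKM (log2 fold change 1.38, adjusted p = 1.755e-05, and 2.43 and 2.68 on the log2 scale with pseudocounts of 0.1 and 0.01). Fcgr3 and Fcgr2b, which encode the CD16 and CD32 of the LSC gate, were lower in the LSC-labelled libraries, at 371 ± 117 against 197 ± 20.7 FPKM and 42.2 ± 5.17 against 26.6 ± 4.13. Kit was higher there (21.5 ± 8.36 against 61.6 ± 2.99 FPKM) and so was Cd34 (27.7 ± 13.3 against 91.3 ± 3.60), which is named in the LSC gate and so went with the labels, while Cd48, at 130 ± 23.0 and 153 ± 11.8 FPKM, did not pass the test (adjusted p = 0.143). Of the 7 sort markers 4 were higher, 2 lower and 1 not called, with the same counts adjusted over the list alone, and as a list they were not called (median log2 fold change 1.38, adjusted p = 0.230, 0.536 with an estimated correlation).

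**Figure D1:**
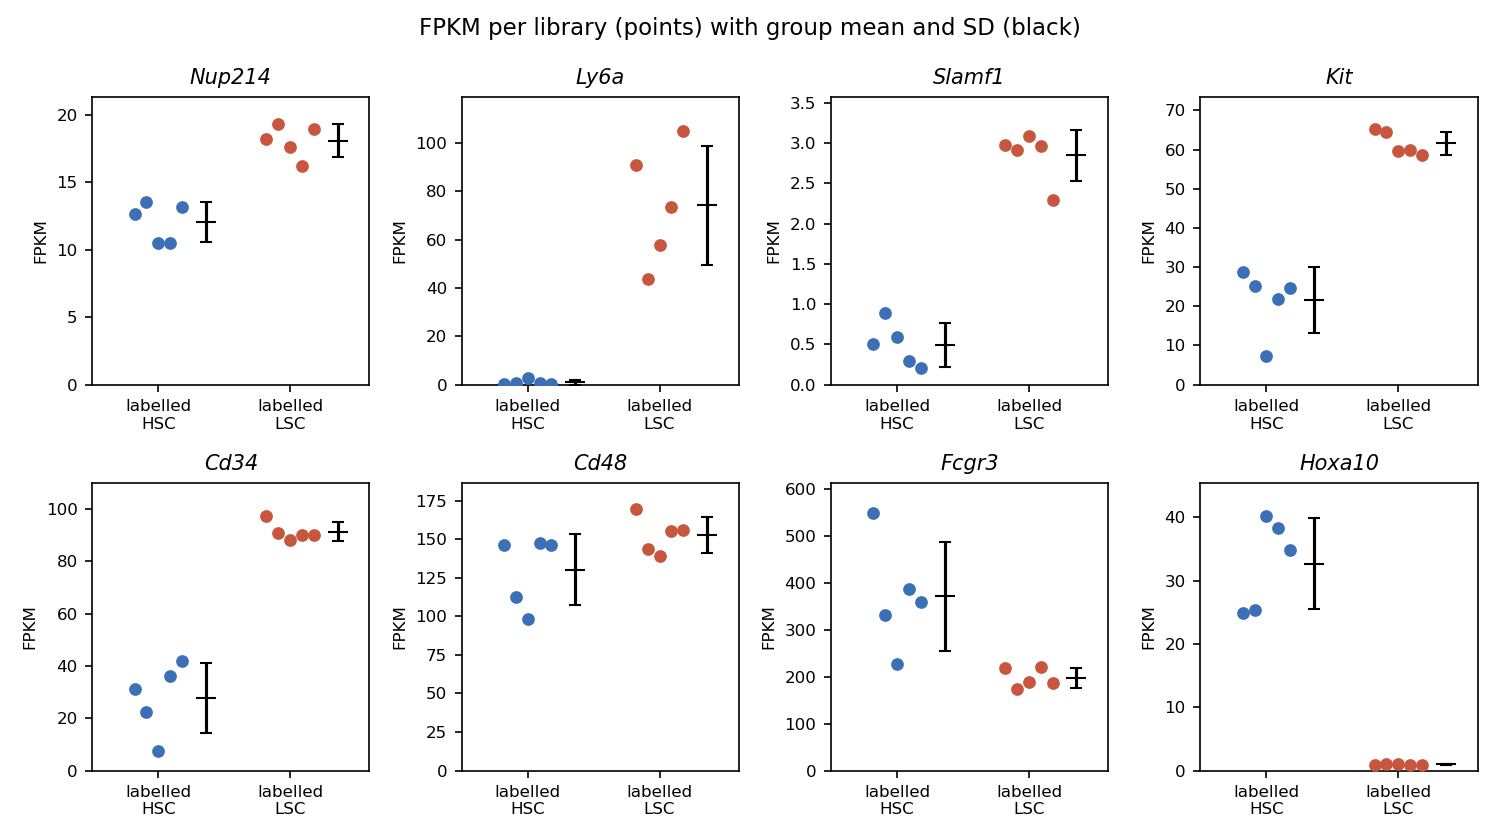
Each panel shows 1 gene, with the FPKM of each library as a point on a linear axis from 0, in the 5 HSC-labelled (blue) and 5 LSC-labelled (red) libraries, and the group mean with its SD in black. Ly6a lies at or below 2.52 FPKM in the HSC-labelled libraries and at or above 43.5 in the LSC-labelled ones, and Hoxa10 lies above 24.9 FPKM in the former and at or below 1.10 in the latter.

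Genes of haematopoietic stem cells were higher in the LSC-labelled libraries. Of the 24 tested, 21 were higher, 1 lower and 2 not called, with the same counts adjusted over the list alone. Ifitm1 rose from 8.31 ± 5.73 to 156 ± 18.0 FPKM, and Cavin2, a protein of caveolae, from 2.06 ± 1.98 to 20.97 ± 6.69. Procr, the stem cell surface receptor EPCR, rose from 0.186 to 1.91 FPKM. Prdm16 was the member that fell, from 3.23 to 1.18 FPKM, while Mecom (0.926 and 1.04 FPKM) and Sult1a1 were not called. The list had a median log2 fold change of 1.70 (camera adjusted p = 5.681e-08; adjusted p = 0.285 with an estimated correlation), and of 2.7025 with a pseudocount of 0.01. Megakaryocyte and erythroid markers, described further on, were higher in the same libraries (medians of 3.30 and 3.34).

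Target genes of MLL fusion proteins were lower in the LSC-labelled libraries, the group whose label names the MLL-AF9 leukaemia. Of 20 tested, 15 were lower, 2 higher and 3 not called, against 15 and 3 adjusted over the list alone. Hoxa10 stood at 32.7 ± 7.17 FPKM in the HSC-labelled and 0.954 ± 0.128 in the LSC-labelled libraries (log2 fold change -4.08, SE 0.142, adjusted p = 1.898e-08), and Hoxa9, the homeobox gene that MLL leukaemias depend on, at 57.0 ± 7.58 and 7.06 ± 0.945. Eya1 stood at 40.7 and 2.48 FPKM. Bcl2 and Tet1 were the higher members. The list had a median of -0.79 (adjusted p = 1.05e-08; adjusted p = 0.151 with an estimated correlation). Because the stem cell genes, Ly6a, Slamf1 and the MLL-fusion targets all ran against the labels, every direction below is given between libraries as labelled, and the labels were not changed.

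Across all genes the 5 libraries of each group stood apart from the other group. Limma tested 13431 genes and called 5513, of which 3654 were higher and 1859 lower in the LSC-labelled libraries. At least a 2-fold change was fitted for 1358 of them, 902 higher and 456 lower. Values did not overlap between the groups for 4002 genes (29.8%), where chance would give 0.79%. The first principal component took 64.1% of the variance and separated the groups. Correlations across genes, which are not independent replicates, were 0.935 to 0.979 within the HSC-labelled, 0.977 to 0.987 within the LSC-labelled and 0.887 to 0.926 between groups. The balance of higher to lower calls rested on the scaling. It was 66.3% higher on the deposited values, where the median of all genes lay at 0.11 on the log2 scale, and 50.8% with median-of-ratios scaling (median -0.01), 49.6% with quantile normalization (-0.02) and 47.8% with GC and length trends removed (-0.02).

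The genes that rose most are known from platelets, basophils and bone. Ppbp, a platelet chemokine, rose from 0.814 ± 0.919 to 183 ± 104 FPKM (log2 fold change 6.61, SE 0.374), and Prss34, a basophil protease, from 10.8 ± 10.5 to 710 ± 265. Bglap and Bglap2, the osteocalcin genes of osteoblasts, rose from 0.237 ± 0.166 to 128 ± 79.5 and from 0.103 ± 0.0988 to 68.6 ± 51.7 FPKM. They are neighbouring, near-identical copies whose reads may be split between them by the counting, so their separate levels are uncertain. Sparc, a matrix protein of bone, rose from 0.343 ± 0.259 to 86.1 ± 51.0. The genes that fell most included Penk, which encodes proenkephalin (112 ± 39.2 to 0.4001 ± 0.242 FPKM, log2 fold change -6.27, SE 0.229), Hpgd, which breaks down prostaglandins (552 ± 291 to 9.97 ± 0.546), and F7, coagulation factor VII (123 ± 127 to 0.645 ± 0.208). Sgip1, an endocytosis adaptor, fell from 42.1 ± 6.11 to 0.667 ± 0.154 FPKM. F7 ranged from 9.82 to 271 FPKM over the HSC-labelled libraries. The rule that picked these genes required a limma call and no overlap between the groups (adjusted p of 0.000221 for F7 and lower for the others).

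Nup214, the nucleoporin on the cytoplasmic face of the nuclear pore named in the series title, was higher in the LSC-labelled libraries. Its gene, ENSMUSG00000001855, lies on chromosome 2 at 31974436 to 32053975 on the plus strand (GRCm38/mm10, GENCODE M21). Its level was 12.1 ± 1.48 FPKM (SD, n = 5) against 18.1 ± 1.23 (n = 5), a ratio of 1.497 and a log2 fold change of 0.55 (SE 0.0954, limma adjusted p = 0.000899). All 5 LSC-labelled values lay above all 5 HSC-labelled ones. The higher Nup214 level stood in the libraries with the higher Ly6a, Slamf1 and Cd34.

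Nucleoporins moved the same way as a group. Of the 30 tested, 19 were higher, 0 lower and 11 not called, and 22 were higher adjusted over the list alone. Ahctf1, which seeds pore assembly on chromatin, rose from 7.31 ± 2.78 to 16.3 ± 2.78 FPKM, and Nup85, of the outer ring of the pore, from 63.5 ± 8.35 to 101 ± 6.67. Nup88, which binds Nup214, rose from 43.4 to 52.6 FPKM. Nup62 (90.2 and 98.3 FPKM) and Tpr (31.4 and 28.7) were not called. The median was 0.36 (adjusted p = 0.000344; adjusted p = 0.423 with an estimated correlation). It fell to 0.23 with median-of-ratios scaling and with quantile normalization and to 0.19 with GC and length trends removed, with 14 members higher and 0 lower in each. Most marker lists of other cell types were called higher in the same libraries, with medians up to 3.34 for erythroid cells. The monocyte and macrophage list was lower (median -0.17), and the B lymphoid and neutrophil lists were not called.

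Of 31 nuclear transport receptors and Ran cycle genes, 15 were higher, 0 lower and 16 not called, with 17 higher adjusted over the list alone. Ipo11, an importin, rose from 9.66 ± 0.907 to 19.8 ± 1.90 FPKM, and Nutf2, which carries Ran into the nucleus, from 80.7 ± 12.8 to 133 ± 5.98. Ran itself rose from 280 to 373 FPKM. Xpo1, the main exporter of proteins (23.9 and 25.1 FPKM), was not called. The median was 0.25 (adjusted p = 0.00109; adjusted p = 0.398 with an estimated correlation), and 0.12 with median-of-ratios scaling and quantile normalization and 0.13 with GC and length trends removed, where 10, 11 and 11 members were higher. Here too most marker lists of other cell types were higher in the same libraries, so a different mix of cells was not set apart.

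Genes that protect cells from ferroptosis, the iron-dependent death by lipid peroxidation, went both ways. Of 26 tested, 13 were higher, 5 lower and 8 not called in the LSC-labelled libraries, with 14 and 5 adjusted over the list alone. Nqo1, a quinone reductase, rose from 1.81 ± 1.93 to 10.98 ± 3.12 FPKM, Gclm, a subunit of the enzyme that starts glutathione synthesis, from 10.5 ± 8.53 to 36.4 ± 10.6, and Gpx4, the lipid peroxide reductase, from 255 to 322 (adjusted p = 0.0195). Aifm2, which encodes the ubiquinone reductase FSP1, fell from 6.85 to 2.49 FPKM, Gsr, glutathione reductase, from 373 to 123, and Ftl1, ferritin light chain, from 1055 to 555. Hmox1 and Pgd also fell. Slc7a11, the cystine transporter, lay below the filter at 0.347 and 0.3598 FPKM. The list had a median of 0.28 and was not called (adjusted p = 0.344, 0.706 with an estimated correlation). Its median ran from 0.11 to 0.34 over all alternatives. With median-of-ratios scaling or quantile normalization 11 were higher and 6 lower, and with GC and length trends removed 11 and 7.

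Among genes that promote ferroptosis, 12 of 22 were higher, 2 lower and 8 not called, with the same counts adjusted over the list alone. Alox12, a lipoxygenase abundant in platelets, rose from 0.302 ± 0.229 to 22.0 ± 12.2 FPKM, and Alox15 from 0.597 ± 0.689 to 9.60 ± 2.74. Their log2 fold changes of 4.03 and 2.79 were 6.36 and 5.19 with a pseudocount of 0.01. Acsl4, which loads membranes with polyunsaturated fatty acids, rose from 5.58 to 9.35 FPKM, and Tfrc, the transferrin receptor of iron-importing cells, from 16.3 to 39.2. Ncoa4, which takes ferritin to lysosomes, fell from 37.5 to 26.04 FPKM, and Sat1 also fell. Platelet and erythroid cells are rich in Alox12 and Tfrc, and their marker lists were higher in the same libraries (medians of 3.30 and 3.34). The median of 0.44 missed the threshold (adjusted p = 0.0545, 0.285 with an estimated correlation). The list passed it in 13 alternatives, among them the runs without HSC-labelled replicate 2 or 3 or LSC-labelled replicate 2 or 5 (medians of 0.46, 0.42, 0.42 and 0.44), and its adjusted p ranged from 3.764e-07 to 0.285 over all of them.

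Iron handling genes showed no common direction, with 5 of 20 higher, 4 lower and 11 not called, both over all genes and adjusted over the list alone. Steap3, the ferrireductase of erythroid endosomes, rose from 6.60 ± 2.25 to 21.3 ± 4.19 FPKM, and Slc11a2, the iron transporter DMT1, from 5.24 ± 1.63 to 14.4 ± 2.37. Hmox1 fell from 91.5 to 49.7 FPKM. The median was 0.16 (adjusted p = 0.987, and 0.987 with an estimated correlation).

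Genes of granulocyte-monocyte progenitors were lower or not called for the most part. Of 25, 2 were higher, 11 lower and 12 not called, with 3 and 11 adjusted over the list alone. Csf2ra, the receptor chain for GM-CSF, fell from 180 ± 22.3 to 38.1 ± 18.3 FPKM, Spi1, the myeloid factor PU.1, from 270 to 120, and Lyz2, lysozyme, from 2635 to 982. Nkg7, a granule protein also found in T and NK cells, rose from 212 ± 164 to 720 ± 119 FPKM. Primary granule genes were abundant in both groups and not called, with Mpo at 2995 and 4826 FPKM and Elane at 9713 and 6526. The median was -0.39 (adjusted p = 0.000545; adjusted p = 0.423 with an estimated correlation) and -0.59 without HSC-labelled replicate 2. The higher members were 1 with median-of-ratios scaling, quantile normalization or GC and length trends removed, 4 with a replicate block and 5 without HSC-labelled replicates 1 and 2. Monocyte and macrophage markers were also lower in these libraries and most other marker lists higher, so a different mix of cells was not set apart.

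The cell-cycle list had 13 of 37 members higher, 1 lower and 23 not called in the LSC-labelled libraries, and 11 and 1 adjusted over the list alone. Ccne1, cyclin E1, rose from 18.5 ± 5.99 to 42.8 ± 10.4 FPKM and Cdc6, which licenses replication origins, from 15.9 ± 3.56 to 27.8 ± 2.90, while E2f1 fell from 10 to 7.05. Mki67 stood at 19.6 and 19.2 FPKM, not called. The number of higher members depended on the setting. It was 2 under median-of-ratios scaling, 5 under quantile normalization and 2 with GC and length trends removed, 7 with a replicate block, without LSC-labelled replicate 5 or without HSC-labelled replicates 3 and 4, and 9 without HSC-labelled replicate 2. The median of 0.25 was not called (adjusted p = 0.154, 0.697 with an estimated correlation), except without HSC-labelled replicate 1 (median 0.25, adjusted p = 0.0229), without the filter and by the fry test (range over alternatives 3.242e-06 to 0.697).

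Cell-cycle inhibitors and quiescence genes had 4 of 19 members higher, 2 lower and 13 not called, with the same counts adjusted over the list alone. Gas6, a ligand of the TAM receptor kinases, rose from 1.39 ± 0.725 to 6.58 ± 3.65 FPKM, and Foxo3, a factor that keeps stem cells quiescent, from 3.46 ± 1.33 to 7.02 ± 0.609. Foxo3 kept its call at a log2 fold change of 0.57 in place of 0.90 without HSC-labelled replicates 3 and 4. Cdkn1a, the inhibitor p21, fell from 27.8 to 15.3 FPKM. Under the 3 scalings (median-of-ratios, quantile, and GC and length trends removed), as without HSC-labelled replicates 3 and 4, 3 were higher and 4 lower. The median was -0.07 and the mean 0.11, and the test, which pointed down, made no call (adjusted p = 0.471, 0.854 with an estimated correlation).

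Genes for ribosome biogenesis and for respiration were higher in the LSC-labelled libraries. Of 25 ribosome biogenesis genes, 18 were higher, 0 lower and 7 not called, and 20 were higher adjusted over the list alone. Gnl3, nucleostemin, rose from 57.5 ± 11.3 to 99.7 ± 13.1 FPKM and Npm1, nucleophosmin, from 510 to 725. Of 28 nuclear-encoded oxidative phosphorylation genes, 22 were higher, 0 lower and 6 not called, with 23 higher adjusted over the list alone. Atp5g1, of the ATP synthase ring, rose from 46.6 ± 7.89 to 81.9 ± 3.28 FPKM. The medians were 0.48 and 0.47 (adjusted p = 0.000216 and 8.398e-05; adjusted p = 0.424 and 0.495 with an estimated correlation), and 0.31 each with GC and length trends removed, where 13 and 15 members were higher and 0 lower. Without HSC-labelled replicates 3 and 4, 13 and 20 were higher, and without LSC-labelled replicate 5, 14 and 18. Most marker lists of other cell types were higher in the same libraries, so a different mix of cells was not set apart. The 13 mitochondrially encoded genes had 2 higher, 0 lower and 11 not called, also adjusted over the list alone, and their list was not called (median 0.23, adjusted p = 0.452, 0.854 with an estimated correlation), except without the filter and, at a median of 0.53, without HSC-labelled replicates 3 and 4 (adjusted p = 0.00641, range over alternatives 0.00497 to 0.914).

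The other metabolic lists were not called. Of 19 glycolysis genes, 5 were higher, 5 lower and 9 not called, with 5 and 7 adjusted over the list alone, and 4 and 7, 5 and 8, and 4 and 8 under the 3 scalings. The lower members were 3 without LSC-labelled replicate 5 or without HSC-labelled replicates 3 and 4. Slc2a3, the glucose transporter GLUT3, rose from 1.95 ± 1.15 to 12.5 ± 2.66 FPKM, and Pkm, pyruvate kinase, fell from 725 to 412. The median was -0.04, the mean 0.16 and the test pointed down (adjusted p = 0.344, 0.536 with an estimated correlation). Of 26 cholesterol and fatty acid synthesis genes, 11 were higher, 2 lower and 13 not called, also adjusted over the list alone (median 0.24, adjusted p = 0.139, 0.697 with an estimated correlation). Under the 3 scalings 8 were higher and 3, 3 and 4 lower, and without LSC-labelled replicate 5, 7 were higher and 1 lower. The median of this list ran from 0.0578 to 0.27 over all alternatives. Fads2, a fatty acid desaturase, rose from 4.22 ± 5.19 to 22.4 ± 4.79 FPKM. Its HSC-labelled mean rested on replicate 2, at 13.4 FPKM, with 0.7055 to 2.98 in the other HSC-labelled libraries. Of 21 genes of the ATF4 and amino acid response, 7 were higher, 0 lower and 14 not called, also adjusted over the list alone (median 0.24, adjusted p = 0.198, 0.697 with an estimated correlation). Under each of the 3 scalings 4 were higher and 1 lower, and the median ran from 0.0176 to 0.32 over all alternatives. Phgdh, which opens serine synthesis, rose from 50.7 ± 14.3 to 279 ± 26.7 FPKM, while Atf4 stood at 77.7 and 73.0, not called.

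Interferon response genes were higher in the LSC-labelled libraries. Of 24, 23 were higher, 0 lower and 1, Mx1, not called, and all 24 were higher adjusted over the list alone. Rtp4 rose from 1.84 ± 1.21 to 55.1 ± 19.3 FPKM, Isg15, a ubiquitin-like modifier, from 1.84 to 35.7, and Irf7, the factor that amplifies the response, from 5.64 to 56.3. The median was 2.16 (adjusted p = 8.029e-12; adjusted p = 0.285 with an estimated correlation). Most marker lists of other cell types, such as dendritic cells (median 1.10), were higher in the same libraries, so a different mix of cells was not set apart. Of 10 MHC class II genes, 3 were higher, 1 lower and 6 not called, with 2 and 1 adjusted over the list alone, and the list was not called (median 0.98, adjusted p = 0.576, 0.858 with an estimated correlation). H2-Ab1, its member named by rule, stood at 94.6 ± 80.3 and 191 ± 54.6 FPKM with an adjusted p that rounds to 0.05, and 21 alternatives ended its call.

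Apoptosis genes had members in both directions. Of 17 p53 targets, 3 were higher, 5 lower and 9 not called, and of 15 BCL2 family genes 3 were higher, 4 lower and 8 not called, with the same counts adjusted over each list alone. Under the 3 scalings the lower members were 8, 7 and 8 p53 targets and 6, 7 and 7 BCL2 family genes. Pmaip1, the BH3-only protein Noxa and a member of both, fell from 24.7 ± 8.64 to 3.89 ± 1.17 FPKM, and Fas, the death receptor, from 7.86 to 2.17. The medians were both -0.04 (adjusted p = 0.0767 and 0.103; adjusted p = 0.439 and 0.398 with an estimated correlation). With a library left out they reached -0.10 and -0.21. Over all alternatives the p53 median ran from -0.20 to -0.0054 and the BCL2 family median from -0.39 to -0.0331. The p53 list passed the threshold without LSC-labelled replicate 3 (median -0.07, adjusted p = 0.0404), at a mean of at least 5 FPKM and by fry. Of 18 immediate early and stress genes, 2 were higher, 2 lower and 14 not called, also adjusted over the list alone. Hsph1, a heat shock protein, rose from 13.8 ± 2.77 to 29.6 ± 3.38 FPKM, and Fos, at 88.5 and 80.9, was not called. Their median was 0.10 and their mean 0.12, while the test pointed down (adjusted p = 0.686, 0.917 with an estimated correlation).

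Markers of other blood and marrow cells, which the lineage-negative sorts would be meant to exclude in mature form, were higher in the LSC-labelled libraries for most lists. All 12 megakaryocyte and platelet markers tested were higher (median 3.30, adjusted p = 5.681e-08; adjusted p = 0.285 with an estimated correlation), with Pf4, platelet factor 4, at 68.1 ± 79.3 and 678 ± 89.3 FPKM. Much of the HSC-labelled mean of Pf4 came from replicate 2, at 205 FPKM, with 8.51 to 62.4 in the other HSC-labelled libraries. Of 15 erythroid markers, 10 were higher, 0 lower and 5 not called (median 3.34, adjusted p = 0.00168; adjusted p = 0.458 with an estimated correlation). Car1, carbonic anhydrase of red cells, stood at 223 ± 460 and 899 ± 357 FPKM, and its HSC-labelled mean rested on replicate 2, at 1046. The 4 globin genes were not called. Of 9 mast cell, basophil and eosinophil markers, 8 were higher and 1 not called (median 3.11, adjusted p = 1.19e-05; adjusted p = 0.285 with an estimated correlation), led by Prss34 and by Mcpt8, a basophil protease (18.2 and 392 FPKM), and with a median of 2.003 without the filter. Counts adjusted over the list alone were the same for the first pair of lists and 9 higher for the third.

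Mature neutrophil markers had 11 of 14 members higher, 1 lower and 2 not called, with 11 and 2 adjusted over the list alone (median 2.51, adjusted p = 0.0507, 0.697 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, stood at 898 ± 711 and 5239 ± 3501 FPKM. Its call ended without HSC-labelled replicates 3 and 4 (log2 fold change 2.05 in place of 2.58, adjusted p = 0.0649), where 6 members were higher and 2 lower. The list passed the threshold in 13 alternatives, including those without HSC-labelled replicate 2 (median 2.98) or LSC-labelled replicate 5 (3.07). Monocyte and macrophage markers had 0 of 14 higher, 6 lower and 8 not called, also adjusted over the list alone (median -0.17, adjusted p = 0.00611; adjusted p = 0.285 with an estimated correlation). Ctss, a lysosomal protease, fell from 205 ± 50.2 to 115 ± 11.9 FPKM. The median was -0.37 without HSC-labelled replicate 2 or without replicate 3, -0.51 without replicates 1 and 2, -0.38 without replicates 3 and 4, and -0.29, -0.30 and -0.36 under the 3 scalings.

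T and NK cell, dendritic and stromal markers were also higher, while B lymphoid markers were not called as a list. Of 8 B lymphoid markers, 5 were higher, 0 lower and 3 not called (median 0.96, adjusted p = 0.139, 0.668 with an estimated correlation), and 4 higher and 2 lower without HSC-labelled replicate 2. Cd79b, of the B cell receptor, stood at 41.1 ± 7.88 and 34.1 ± 4.85 FPKM and was not called, except without HSC-labelled replicate 2 (log2 fold change -0.36, adjusted p = 0.0306) and with GC and length trends removed together with a block for the replicate number (-0.40, adjusted p = 0.0184). Of 8 T and NK cell markers 7 were higher and 1 not called (median 1.599, adjusted p = 0.000619; adjusted p = 0.285 with an estimated correlation), with Nkg7 the most abundant and Gzma, a granzyme, at 1.03 and 15.7 FPKM. The median was 2.53 and 2.75 with pseudocounts of 0.1 and 0.01 and 0.97 without the filter. Of 11 dendritic cell markers 7 were higher and 4 not called (median 1.10, adjusted p = 0.00908; adjusted p = 0.398 with an estimated correlation), a list call that ended without HSC-labelled replicates 1 and 2 (median 1.15, adjusted p = 0.0680). Bst2, also an interferon response gene, rose from 62.4 ± 13.7 to 262 ± 60.6 FPKM. Of 10 endothelial and stromal markers 9 were higher and 1 not called (median 1.39, adjusted p = 0.000216; adjusted p = 0.285 with an estimated correlation), with Col1a1, bone collagen, at 0.416 ± 0.199 and 88.2 ± 78.1 FPKM, and a median of 2.91 and 3.42 with pseudocounts of 0.1 and 0.01. Col1a1 reached 224 FPKM in LSC-labelled replicate 1 and 27.8 to 77.1 in the other LSC-labelled libraries. Counts adjusted over the list alone were the same for these 4 lists.

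The sex-linked genes were read as a check on the animals and, with 4 members tested, not as a list. Xist lay at or below 0.0562 FPKM in all 10 libraries. Eif2s3y stood at 7.39 ± 9.46 FPKM in the HSC-labelled and 24.5 ± 2.03 in the LSC-labelled libraries (log2 fold change 2.15, adjusted p = 0.00478) and was the 1 member called, over all genes and adjusted over the list alone. Ddx3y (15.8 ± 6.503 and 18.0 ± 1.88 FPKM), Kdm5d (2.51 ± 1.06 and 2.80 ± 0.308) and Uty (5.42 ± 2.19 and 6.48 ± 0.876) were not called.

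**Figure D2:**
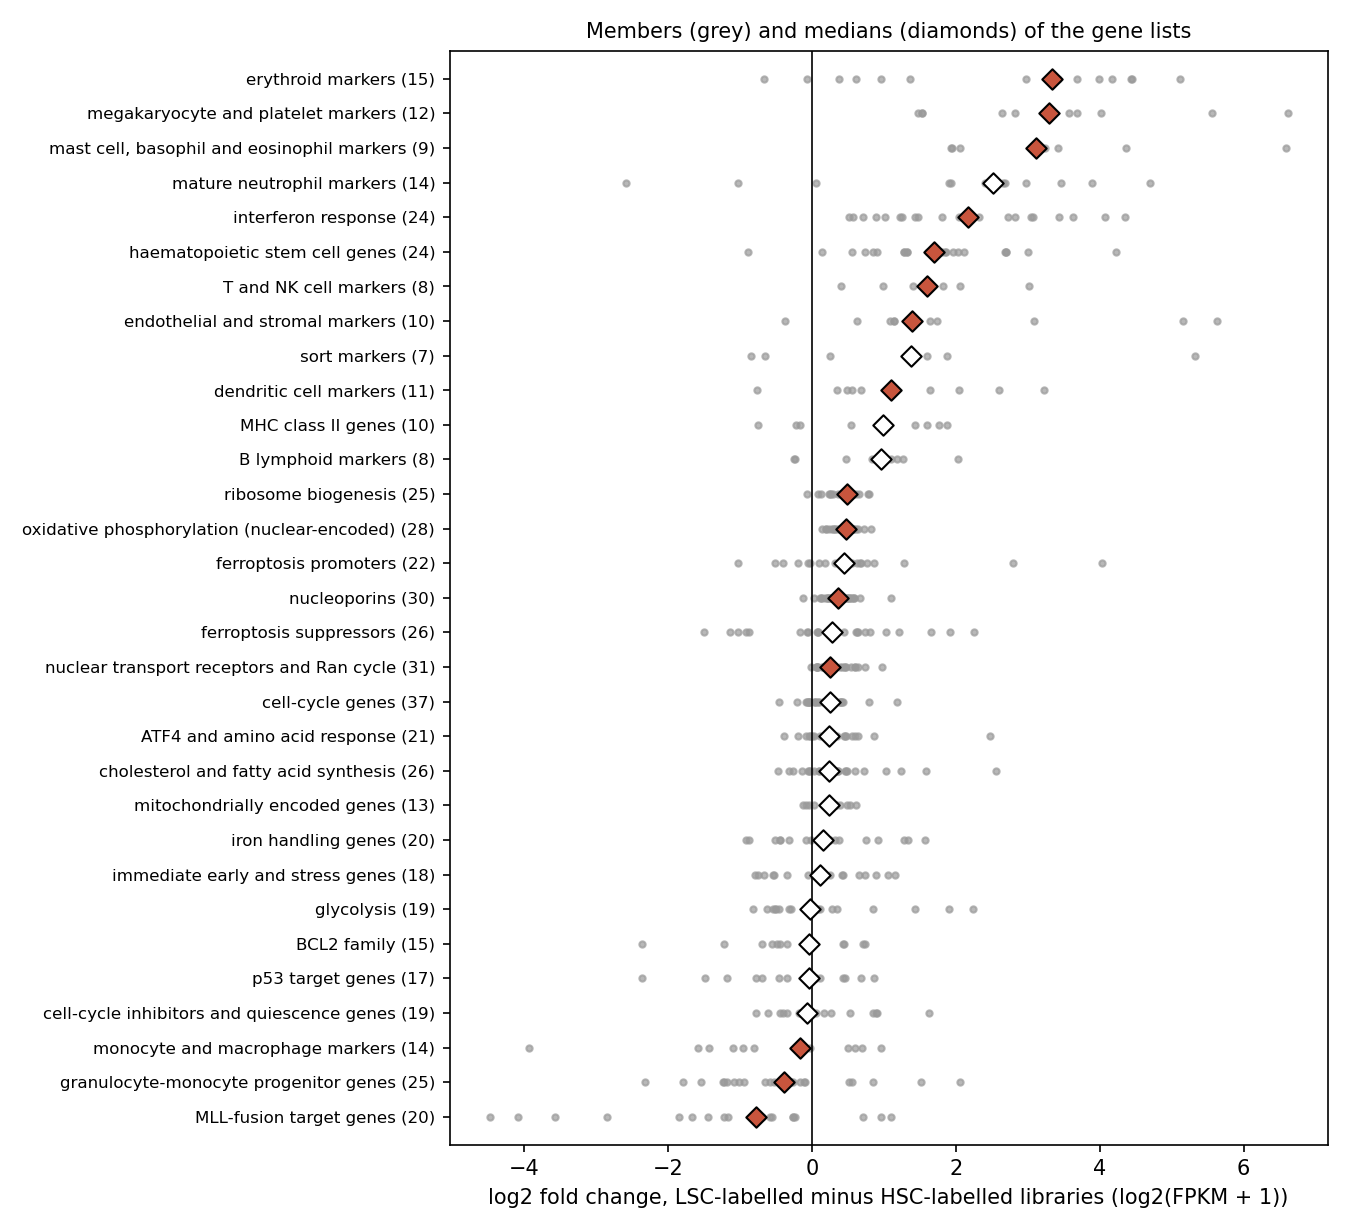
Log2 fold changes on the log2(FPKM + 1) scale, LSC-labelled minus HSC-labelled libraries, for the members of the 31 gene lists tested (grey points, number tested in parentheses) with each list's median as a diamond, red where the camera test with a preset correlation called the list and white where it did not. Medians run from -0.79 for the MLL-fusion targets to 3.34 for the erythroid markers, and 15 lists are red, 12 of them higher and 3 lower.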

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

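The tests of explanations in this part, including the other splits of the libraries, were chosen only after the results they bear on had been seen. A library was picked out where it lay far from the other 4 of its group by Dixon's ratio, over the named genes tested and the list means. The measures of library quality were not screened in this way. Chance picks out about 1 in 20 groups, so of 178 groups 8.9 would be expected, and 15 were found, 6 of them in HSC-labelled replicate 2 and 4 in HSC-labelled replicate 1.

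In HSC-labelled replicate 2, Car1 stood at 1046 FPKM (10 to 26.2 in the other 4), Ifitm1 at 18.5 (4.66 to 6.57), Nqo1 at 5.25 (0.732 to 1.13) and Steap3 at 10.6 (5.20 to 6.31). The mean log2 level of the erythroid markers was 5.04 there (2.30 to 2.73 in the others) and that of the neutrophil markers 5.88 (3.91 to 4.45). In HSC-labelled replicate 1, 3 genes of the Y chromosome were low, Ddx3y at 4.31 FPKM (17.5 to 20.4 in the other 4), Kdm5d at 0.732 (2.58 to 3.53) and Uty at 1.54 (6.07 to 6.79), and Sparc was high at 0.802 (0.180 to 0.258). Kit was low in HSC-labelled replicate 3, at 7.22 FPKM (21.9 to 28.6). Among the LSC-labelled libraries, Slamf1 was low in replicate 5 at 2.29 FPKM (2.91 to 3.09), Foxo3 low in replicate 4 at 5.97 (7.07 to 7.49) and Phgdh high in replicate 1 at 325.7 (259.3 to 274.3). The endothelial and stromal mean of replicate 1 was also high, at 3.88 (2.88 to 3.16).

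Ly6a, Slamf1, Fcgr3 and Fcgr2b among the sort markers, and the MLL-fusion targets as a list, ran against the group labels. Cd34, named in the LSC gate, went with them, at 27.7 FPKM in the HSC-labelled and 91.3 in the LSC-labelled libraries. Labels that are right, with groups that differ as their names say, need the haematopoietic stem cell list below 0. Its median was 1.70 ± 0.265 (SE over members), which argues against such labels for this list. The list is itself among the values that raised the question, and its camera call was lost with an estimated correlation (adjusted p = 0.285). Megakaryocyte and erythroid markers rose in the same libraries too, so the list alone does not decide it. An exchange of the group labels stays open. Of the 6 sort markers that a single gate names, 1 was called with the labels (Cd34), 4 against them and 1 not called (Cd48). The 4 are among the values that raised the idea of an exchange, so they cannot also test it. They do run against what the labels as given require, with Ly6a at 0.920 FPKM in the HSC-labelled and 74.2 in the LSC-labelled libraries. Cd34 runs the other way. Cd48, at 153 FPKM in the LSC-labelled libraries, runs against an exchange with libraries made of the stated stem cell gate alone. It runs against the labels as given in the same way, at 130 FPKM in HSC-labelled libraries whose gate excludes it. Cd48 therefore favours neither reading. These are RNA levels, while the gates were set on surface protein, which was not measured here. The granulocyte-monocyte progenitor list, with a median of -0.39 ± 0.248 (SE over members), did not reach the fall of 2 or more that was set. That limit was assumed after the values were seen and was not measured, so the list does not decide it. What stays open is whether the LSC-labelled libraries hold normal progenitors of a wider gate, which no table here decides.

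The erythroid genes of HSC-labelled replicate 2 stood out from the other HSC-labelled libraries, and the lineage-negative step and, for the HSC gate, Sca-1 would remove most erythroid cells. An even admixture of all the cells of the LSC-labelled libraries is argued against by the mast cell, basophil and eosinophil markers. Shares were computed only for markers clearly higher in the LSC-labelled than in the other HSC-labelled libraries. These were 9 of the 15 erythroid markers, without the globins, 9 megakaryocyte and platelet markers and 6 mast cell, basophil and eosinophil markers. The median rise of the last 6 above the other HSC-labelled libraries was -1.95% of the LSC-labelled level (highest -0.10%). The 9 erythroid markers reached 39.7% (21.3% to 122.8%). The excess was not erythroid alone, as megakaryocyte and platelet markers reached a median of 19.9% (-0.2% to 44.3%), with Itga2b at 44.3% and Pf4 at 26.6%. Admixture of only some cell types of the LSC-labelled libraries stays open, since the mast cell, basophil and eosinophil markers cannot exclude it. Globin-making cells stay open. Of the 4 globin genes 0 lay above every other HSC-labelled library, but these held globins too (Hba-a1 at 29.6 to 158.7 FPKM, 70.8 in replicate 2), which would hide a small share. The 11 other erythroid markers, with Car2 at 326 FPKM and Klf1 at 54.3, all lay above the other libraries, but it was these markers that picked the library out, so which cells the transcripts came from stays open. The design gives a single library no biological explanation to test.

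Nucleoporin genes were higher in the LSC-labelled libraries. Scaling between libraries as the whole cause is argued against, since with median-of-ratios scaling, which put the median of all genes at -0.01, the list kept a median of 0.23 ± 0.053 (SE), with 14 members higher and 0 lower. GC and length trends as the whole cause are argued against too, since with them removed the list was still called at the preset correlation, with a median of 0.19 ± 0.053 (adjusted p = 0.00103). Both SEs are over the list's members on the deposited values, taken as independent, so they understate the error where members move together. On the deposited values the call was lost with an estimated correlation (adjusted p = 0.423, median 0.36 as before), the highest value over all alternatives, which began at 4.134e-14. A different mix of cell types cannot be told apart from a change within cells, because 7 of 9 marker lists of other cells were called between the same groups at the preset correlation. With an estimated correlation 0 of these lists were called. The difference between leukaemic and normal cells that the design names may also underlie it, untested here while the labels stand in doubt. That difference cannot be told apart from the difference in sort gate.

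Among 100 of the 126 ways to part the 10 libraries into 5 and 5, only the real one, 1 of 100, gave as many as 5513 genes, and the highest of the others gave 4. Every other split mixes libraries of both labels, which widens its spread within groups, so few calls were bound to follow there. The labels do not say whether the libraries came from separate mice. A chance difference between animals or batches is therefore not excluded.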

How the results depend on the processing

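The alternatives were fixed before the data were examined, except the runs without HSC-labelled replicates 1 and 2 and without replicates 3 and 4, which were chosen after seeing the data. Nup214 was called higher in all 25, at 0.41 to 0.63 on the log2 scale (adjusted p 0.000478 to 0.00396). Of 1418 values of 57 genes, 1389 kept direction and call, and of 833 values of 31 lists 749 did. Where no reason is given the cause of a change was not tested. Leaving out each library gave 4659 to 5872 changed genes, and leaving out HSC-labelled replicates 1 and 2 or 3 and 4 gave 5859 and 4795. With a mean of at least 5 FPKM, 3657 of 8226 genes were changed, 1203 lower and 751 at least 2-fold, as fewer genes were tested. The lower genes were 2833 with quantile normalization and 3006 with GC and length trends removed, settings that centre the fold changes near 0.

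No clear pairing of the libraries by their shared replicate numbers was seen, and the labels do not say whether the numbers pair the groups. Own-number correlations of deviations were 0.107, 0.12, -0.29, 0.225 and 0.0520, and the best partner carried the same number for replicates 1 and 4 alone. A replicate block gave 5155 changed genes, 4970 of them shared with the fit without it, and changed the call of 1 list, the neutrophil markers (median 2.51, adjusted p = 0.0257, range 1.446e-06 to 0.697 over alternatives). It changed no other list call. Among list members, it took the higher cell-cycle genes from 13 to 7, the higher nuclear transport genes from 15 to 11, the higher nucleoporins from 19 to 17, the lower MLL-fusion targets from 15 to 14 and the higher interferon response genes from 23 to 24. Higher granulocyte-monocyte progenitor genes went from 2 to 4, higher ATF4 response genes from 7 to 9, higher monocyte and macrophage markers from 0 to 1 and higher mitochondrially encoded genes from 2 to 1. Counts of further lists moved by at most 1 in either direction.

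With an estimated correlation, all 15 list calls were lost because a larger correlation among members widens the error while the medians stay: haematopoietic stem cell genes 1.70, MLL-fusion targets -0.79, granulocyte-monocyte progenitor genes -0.39, nucleoporins 0.36 and nuclear transport 0.25. Fry and the run without a filter, where most genes lie near 0, called lists that the main fit did not: sort markers (1.38 in both), ferroptosis suppressors (0.28 and 0.27), ferroptosis promoters (0.44 and 0.41), iron handling (0.16 and 0.18) and cell-cycle genes (0.25 in both), and among the further lists also cholesterol and fatty acid synthesis, the ATF4 response, B lymphoid and neutrophil markers in both, p53 targets and the BCL2 family by fry, and MHC class II and mitochondrially encoded genes without a filter. Some of these were called in other alternatives too: cell-cycle genes without HSC-labelled replicate 1, p53 targets at a mean of at least 5 FPKM and without LSC-labelled replicate 3, and mitochondrially encoded genes without HSC-labelled replicates 3 and 4. The ferroptosis promoters were called on the TPM scale (0.44), with median-of-ratios scaling (0.30), quantile normalization (0.31), GC and length trends removed with or without the block (0.30), X and Y left out (0.49) and without HSC-labelled replicates 3 and 4 (0.40). With each library left out their median ran from 0.41 to 0.47 and that of the cell-cycle genes from 0.19 to 0.25. Over all alternatives the ferroptosis promoters ran from 0.30 to 0.485 and the cell-cycle genes from 0.0554 to 0.253.

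Test directions turned only for results that were not called. For fry and no filter, the quiescence list turned at medians of -0.073 and -0.0351 and glycolysis at -0.0353 and -0.064. The iron list turned at a mean of at least 5 FPKM (0.091) and in 4 runs with a library left out (0.0806 to 0.23 over all). The immediate early list turned by fry (0.10), without a filter (0.0769), with median-of-ratios scaling (0.0063), quantile normalization (-0.0475), GC and length trends removed (0.0419) and without HSC-labelled replicates 1 and 2 (0.35), and ran from -0.0442 to 0.25 with a library left out. MHC class II turned at a mean of at least 5 FPKM (1.17) and, like the mitochondrially encoded genes (0.11), without HSC-labelled replicates 1 and 2 (0.72). That run also turned Ddx3y (-0.0777), Kdm5d (-0.0791) and Uty (-0.0058). Ddx3y ran from -0.0499 to 0.45 and Kdm5d from -0.057 to 0.29 with a library left out, lowest without HSC-labelled replicate 1, where they were low. Smaller pseudocounts widened folds of low genes, Bglap2 to 9.98 at 0.01. The shallowest library, at an estimated 13280000 fragments, limits what can be read below 1 FPKM.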

Other observations

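Apart from F7, Hoxa10 and Eif2s3y, the genes in this part were chosen after their values were seen, and it holds values with no test of an explanation. The clustered Hox genes, which pattern the body axis and mark myeloid leukaemias, were expressed from the Hoxa cluster and hardly from the others. On chromosome 6, 6 of 11 Hoxa genes passed the filter and all 6 were lower in the LSC-labelled libraries, in an unbroken run from Hoxa5 (6.39 ± 1.47 against 1.04 ± 0.261 FPKM) to Hoxa10, with Hoxa3 as the sixth (2.16 against 0.324). None of the 10 Hoxb, 9 Hoxc and 8 Hoxd genes passed the filter, at mean levels over all libraries of at most 0.717, 0.165 and 0.0840 FPKM. Igf2bp3, an RNA-binding protein of fetal and leukaemic cells, stood at 21.8 ± 1.998 FPKM in the HSC-labelled and 1.46 ± 0.373 in the LSC-labelled libraries (log2 fold change -3.22, limma adjusted p = 1.898e-08), with all 5 values on either side apart.

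A few genes were high in HSC-labelled replicates 3 and 5 and lower in the other HSC-labelled libraries. F7 stood at 271 and 251 FPKM in these and at 9.82 to 43.7 in the other 3, Hoxa11 at 3.36 and 6.35 against at most 0.347, and Hoxb13 at 3.86 and 2.52 against at most 0.262. In the LSC-labelled libraries F7 stayed at or below 0.850. Eif2s3y, on the Y chromosome, stood at 24.1 FPKM in HSC-labelled replicate 2, at 1.90 to 5.71 in the other HSC-labelled libraries and at 21.5 to 26.6 in the LSC-labelled ones.

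Plasma cell transcripts varied within both groups. Igkc, the kappa light chain constant gene, stood at 256 FPKM in HSC-labelled replicate 2 and at most 5.17 in the others, and in the LSC-labelled libraries at 22.7 in replicate 4 and from 640 to 1297 in the rest. Jchain, which joins secreted antibodies, showed the same split, at 10.7 FPKM in HSC-labelled replicate 2, 0.0799 in LSC-labelled replicate 4 and 14.5 to 49.1 in the other LSC-labelled libraries. The variable genes Ighv1-55 and Igkv8-27 stood at 102 and 186 FPKM in HSC-labelled replicate 2 and at or below 0.773 and 1.24 in the other 9 libraries. Chil3, a chitinase-like protein of myeloid cells, reached 11533 FPKM there and 190 to 1654 in the other HSC-labelled libraries. Gm10800, an unnamed gene model, reached 8590 FPKM in HSC-labelled replicate 3 and 3567 in replicate 4, the libraries with the highest ribosomal RNA shares (9.26% and 9.33%).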
